A study of Mus musculus with 12 samples.

How the data were processed

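RNA was sequenced from RAW264.7 cells, a mouse macrophage-like line, in 4 groups of 3 libraries: untreated, anti-CD36 antibody (dilution 1 in 100), LPS (50 ng/ml) and both together. One table of gene values was used, with 1 column per library and 31801 entries named by gene symbol. Its values are FPKM (fragment counts scaled by gene model length and by library depth), computed by the authors. Per the submitters' processing notes HISAT2 2.0.5 was used, and the notes name the genome builds mm39 and hg38 without their roles. The counting tool, the annotation and any filter are not stated there.

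The FPKM values of each library fell on whole multiples of a step, so the depth of each library and the number of fragments behind each value were recovered from the steps with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Of the 18167 entries above 0 in at least 1 library, 18165 (99.99%) were whole fragments in every library, within a tolerance of 0.005 fragments. At the exon-union length of the mouse annotation GENCODE M21, 91.9% of them were whole. For the rest a length was searched, and any that made the values whole was accepted. Entries above 0 in few libraries can meet that by chance, so the share at the annotated length is the stricter check. Recovered depths ran from 30070450 to 54137810 fragments. For a gene model of 2000 bases, 1 FPKM stood for 60.1 fragments at the lowest depth (counting coefficient of variation 12.9%) and 108.3 at the highest (9.6%). These figures cover counting error only.

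The 2 entries that were not whole were Il6 and Il1b. In the untreated and anti-CD36 libraries the Il6 values were those of another entry, Gm10874, so Il6 was left out of every comparison except LPS+anti-CD36 versus LPS. Il1b was kept, since 1 of its 12 values was affected and it lay near 0. Where a symbol occurred more than once, the entry of highest mean was kept, which left out 82 entries.

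Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested: 10277, or 10276 where Il6 was left out. One limma model (limma 3.58.1, R 4.3.3) of the 4 group means was fitted with an intensity trend on the prior variance. It gave 4 pairwise comparisons and the interaction, the difference between the LPS change with and without the antibody. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, per comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates those of genes at low levels. All p-values measure only the spread between these libraries, since the labels do not say whether the 3 libraries of a group came from separate cultures. The labels gave no pairing of replicate numbers, so the main fit used no block. In their deviations from the group means, libraries of the same number correlated in part. All pairs of replicate 1 did so, by 0.45 to 0.78, while those of replicate 2 ran from −0.32 to 0.43. In replicate 3 the untreated, LPS and LPS+anti-CD36 libraries correlated by 0.54 to 0.81. Pairs with anti-CD36 replicate 3 ran from −0.07 to 0.03. A block on the replicate number was run as an alternative.

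Gene lists for macrophage activation, lipid and energy metabolism, stress, cell cycle, other cell types and RNA quality were fixed before the data were examined, together with the comparisons, tests, thresholds and most of the alternatives. The 31 lists with at least 3 tested genes were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes moved one way without comparing them with other genes, were run beside it. Counts of called members were also made with p-values adjusted over the list alone. Ranges given after the median of a gene set are 95% bootstrap intervals over its genes, which leave out the spread between libraries.

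Genes named in the text were chosen by a rule fixed in advance. In each pairwise comparison it takes Cd36, Tlr4, Cd14, Tnf, Il6, Il1b and Nos2. It adds the 6 risers and 6 fallers of largest change among called genes whose groups did not overlap and whose higher group had a mean of at least 2 FPKM, without predicted genes and pseudogenes. It also takes up to 4 members of smallest p of every list that passed the set test or had at least 3 called members. In the interaction it takes the 4 genes of smallest p in each direction.

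The overlaps between comparisons were set beside the product of the list sizes over the genes tested and beside 100 simulations of unchanged groups that shared the same libraries. The fit was also tested on simulated data with the recovered depths and the spread of each gene in these libraries, in which 200 genes were changed. For anti-CD36 versus untreated it recovered 20% of the 50 genes changed by 1.25-fold, 72% at 1.5-fold, 92% at 2-fold and 98% at 4-fold. For LPS+anti-CD36 versus LPS the shares were 26%, 72%, 84% and 100%. In each simulation 8 unchanged genes were called. Each gene was drawn on its own, without variation shared across genes, whereas 70.6% of the real within-group variance lay on 1 component. These shares and the 8 calls therefore do not cover shared variation.

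The alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, TPM, median-of-ratios and quantile scaling, constant and robust priors, a fit of only the compared groups, a replicate block, a 2-fold threshold and leaving out each library in turn. Added after the data were seen were removal of the GC content and gene length trend of each library (a local regression over both), the GC slope of each library as a covariate, limma-voom on the recovered fragments and leaving out the 3 libraries of lowest GC slope. GC content and length were known for 10101 of the tested genes (98.3%). A list of 22 targets of hypoxia-inducible factor, none of them in the glycolysis list, was also added after the data were seen. Figures were drawn with matplotlib 3.10.9.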

Results

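Gene expression was measured by RNA sequencing in RAW264.7 cells, a mouse macrophage-like line. The 12 libraries fell into 4 groups of 3: untreated cells, cells given an antibody against CD36 at a dilution of 1 in 100, cells given LPS at 50 ng/ml, and cells given both. LPS is a bacterial cell wall component that activates macrophages through TLR4, and CD36 is a scavenger receptor and fatty acid transporter. The stated purpose was to compare expression between these treatments. The groups held no isotype control antibody, and the labels gave no treatment time. Depth ran from 30070450 fragments in untreated replicate 2 to 54137810 in untreated replicate 1, and between 14228 and 14894 genes were above 0 per library. Values below are mean FPKM ± SD with n = 3 libraries per group, and changes are on the log2(FPKM + 1) scale.

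Cells given LPS alone were compared with untreated cells to show the LPS response of the line. The chemokine Cxcl2, which attracts neutrophils, stood at 424.5 ± 36.7 FPKM with LPS and 0.359 ± 0.0986 without. Il1b, the precursor of a fever-inducing cytokine, stood at 306 ± 25.9 against 0.0484 ± 0.0194, and Il1a at 222 ± 46.1 against 0.00936 ± 0.0162. The untreated SD of Il1b is too small, since its value in untreated replicate 2 equalled the mean of the other untreated replicates. Acod1, which makes the antimicrobial metabolite itaconate, rose from 6.09 ± 0.4 to 1069 ± 137, and Ptgs2, the inducible prostaglandin synthase, from 2.91 ± 0.861 to 830 ± 253. Nos2, the inducible nitric oxide synthase, rose from 3.45 ± 0.237 to 188 ± 20.8, and Tnf from 52.5 ± 3.66 to 1176 ± 134. Cd36 itself (chromosome 5, 17781690 to 17888801 in the GENCODE M21 annotation) rose from 0.17 ± 0.0405 to 5.86 ± 1.47, a log2 change of 2.53 (adjusted p = 3.07e-08).

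All 16 tested inflammatory cytokine genes rose (median log2 change 4.22, adjusted p = 1.89e-22), and so did 13 of 14 chemokine genes, with 1 lower (3.66, adjusted p = 1.49e-15). Of 24 NF-kB targets and feedback regulators, 21 rose and 1 fell, among them Nfkbiz (log2 change 4.22) and Socs3 (3.94), which feed back on cytokine signalling. Of 39 interferon-stimulated genes 38 rose, such as Zbp1 (4.43) and Rsad2 (3.31). All 10 guanylate-binding proteins and related GTPases rose (adjusted p = 2.36e-09, or 0.0668 with an estimated correlation). Of 20 classical activation effectors 18 rose, and 17 of 19 genes of class I antigen presentation rose (adjusted p = 6.72e-09, or 0.104 with an estimated correlation). Adjusted over the list alone, the counts of these 7 lists were the same. Cd14, the LPS co-receptor, rose from 529 ± 74.5 to 1569 ± 266, while Tlr4 fell from 10.3 ± 2.14 to 7.07 ± 1.7 (adjusted p = 0.0297, not past in 6 of 27 settings).

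Genes of cell division moved together in the other direction. All 30 tested genes of DNA replication fell (median −0.96, adjusted p = 2.04e-10), such as Mcm7, part of the replicative helicase (from 77.8 ± 5.17 to 31.6 ± 2.51). All 30 tested genes of mitosis fell as well (median −1.64, adjusted p = 8.43e-15), such as the kinase Plk1 (from 51.1 ± 6.42 to 8.22 ± 1.65) and the cyclin Ccna2 (from 66.5 ± 1.76 to 13.9 ± 0.761). The largest falls outside these lists included Cd24a, a surface glycoprotein (from 31.3 ± 3.07 to 2.37 ± 0.419), and Trem2, a lipid-sensing receptor (from 38.6 ± 7.18 to 5.71 ± 1.4). In cholesterol synthesis and uptake 15 of 25 genes fell and 1 rose (adjusted p = 0.029, or 0.127 with an estimated correlation), and in fatty acid synthesis 10 of 16 fell and 1 rose (adjusted p = 0.0111, or 0.173 with an estimated correlation). In oxidative phosphorylation 18 of 36 genes fell (adjusted p = 0.0169, or 0.644 with an estimated correlation), and 8 of 13 mitochondrially encoded mRNAs fell (adjusted p = 0.0308, or 0.562 with an estimated correlation). In glycolysis 8 of 24 genes rose and 3 fell (adjusted p = 0.0308, or 0.383 with an estimated correlation), with the glucose transporter Slc2a1 rising from 47.8 ± 3.59 to 152 ± 18.9.

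Among the other lists that passed, 20 of 26 immediate early genes rose and 4 fell (adjusted p = 7.22e-13, or 0.065 with an estimated correlation), and 14 of 30 stress response genes rose and 1 fell (adjusted p = 3.32e-05). Of 6 alternative activation markers tested, out of 20 listed, 4 rose, among them Myc, a growth regulator, and Vegfa, an angiogenic factor (adjusted p = 0.00043). The untested ones reached at most 1.03 FPKM. In the inflammasome list 8 of 15 rose and 2 fell (adjusted p = 0.000137, or 0.107 with an estimated correlation), and in the Fc gamma receptor list 12 of 21 rose and 5 fell (adjusted p = 0.00554, or 0.104). In the list of fatty acid uptake and lipid droplets 10 of 24 rose and 5 fell, with the fatty acid carrier Fabp4 rising from 1.51 ± 0.391 to 18.8 ± 0.757 (adjusted p = 0.0169, or 0.0605). The last 3 were macrophage identity (9 of 19 higher, 4 lower, adjusted p = 0.0111, or 0.191), dendritic cell markers (3 of 3 tested higher, out of 14 listed, adjusted p = 0.00115) and TLR4 signalling (9 of 30 higher, 7 lower, adjusted p = 0.0274, or 0.505), each second value with an estimated correlation. The 8 lists that did not pass included fatty acid oxidation (1 of 23 higher, 13 lower, adjusted p = 0.0574) and NRF2 targets (6 of 22 higher, 11 lower, adjusted p = 0.415), whose median was −0.27 and mean 0.13. The other 6 were scavenger receptors (adjusted p = 0.111), LXR targets (0.962), class II antigen presentation (0.711), lysosome and autophagy (0.626), osteoclast markers (0.55) and ribosomal proteins, with 0 of 32 called by limma and a median of −0.12, close to that of all genes, where the direction of the set test differed between scalings.

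Over all genes, 1710 were higher and 3403 lower with LPS among 10276 tested, 49.8% of them, and 957 changed at least 2-fold (526 higher, 431 lower). The median of all genes moved by −0.14, so a gene with no change relative to the others sat near that value. With median-of-ratios scaling, which removes this shift, 2312 were higher and 2245 lower, so the higher share was 50.7% in place of 33.4%. Of the 31 lists 23 passed, 17 up and 6 down, and 10 passed with an estimated correlation. Splits that mixed the untreated and LPS libraries passed up to 21, so the number of lists says little by itself.

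Cells given the antibody alone were compared with untreated cells to show what it changed without LPS. Scd1 (chromosome 19, 44394455 to 44407879), which makes monounsaturated fatty acids, fell from 44.8 ± 4.69 to 18.9 ± 1.62 FPKM (log2 change −1.20, adjusted p = 0.000533). Its relative Scd2 fell from 266 ± 27 to 140 ± 22.2 (adjusted p = 0.0129), and Insig1, an SREBP target whose product restrains SREBP processing, from 30.3 ± 1.55 to 17.1 ± 2.6 (adjusted p = 0.0129). C5ar1, the receptor for complement C5a, rose from 4.59 ± 0.291 to 8.46 ± 0.746 (adjusted p = 0.0318), and the chemokine Ccl3 from 131 ± 14.4 to 200 ± 5.52 (adjusted p = 0.036). Cd36 stood at 0.379 ± 0.111 with the antibody and 0.17 ± 0.0405 without (log2 change 0.23, adjusted p = 0.337).

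In the list of cholesterol synthesis and uptake 4 of 25 genes fell over all genes tested, and 17 fell with p-values adjusted over the list alone (median −0.36, adjusted p = 2.82e-12, and 0.0048 with an estimated correlation). Besides Insig1 these were the enzymes Lss (from 9.44 ± 0.581 to 6.29 ± 0.431), Msmo1 (from 35.7 ± 1.34 to 26.9 ± 1.14) and Cyp51 (from 37.5 ± 2.89 to 25 ± 3.3). In fatty acid synthesis 3 of 16 fell, and 9 fell adjusted over the list alone (median −0.26, adjusted p = 8.74e-06, or 0.118 with an estimated correlation). Acly, which supplies acetyl-CoA for both pathways, fell from 70.3 ± 4.65 to 49.8 ± 4.45. In the chemokine list 2 of 14 rose, and 8 rose adjusted over the list alone (median 0.31, adjusted p = 3.04e-06, or 0.368 with an estimated correlation). The second was Cxcl2, from 0.359 ± 0.0986 to 1.29 ± 0.0657. Among genes outside these lists, Acp5, Angptl2, Dhrs3 and Pck2 rose, with log2 changes of 0.63 or 0.64, and Klhl11 (−1.08), Pdpr (−0.82) and Ak4 (−0.67) fell.

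Inflammatory cytokine genes had a median of 0.08, with 0 of 16 called and 6 higher adjusted over the list alone (adjusted p = 0.00609, or 0.125 with an estimated correlation). Tnf stood at 67.5 ± 4.41 against 52.5 ± 3.66 (adjusted p = 0.139), Il1b at 0.123 ± 0.044 against 0.0484 ± 0.0194 (adjusted p = 0.465) and Nos2 at 3.58 ± 0.198 against 3.45 ± 0.237 (adjusted p = 0.767). For Il1b the untreated SD is too small, as said above. Tlr4 stood at 7.42 ± 0.966 against 10.3 ± 2.14 (adjusted p = 0.226) and Cd14 at 639 ± 31.7 against 529 ± 74.5 (adjusted p = 0.281). Glycolysis genes had a median of −0.15 with 0 of 24 called (adjusted p = 0.00898, or 0.406 with an estimated correlation). Osteoclast markers had a median of 0.14 with 1 of 10 higher, Acp5 (adjusted p = 0.00685, or 0.118 with an estimated correlation). The list test also passed upward, with 0 genes called, for oxidative phosphorylation (adjusted p = 0.00362), ribosomal proteins (0.00405), class I antigen presentation (0.00554) and immediate early genes (0.0138), each 0.55 with an estimated correlation, and for macrophage identity (0.0302) and interferon-stimulated genes (0.0461), each 0.406. With the GC content and gene length trend of each library removed, the adjusted p was 0.149 for oxidative phosphorylation and 0.188 for ribosomal proteins, and each took the other direction in 1 of 27 settings.

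In all, 15 genes were higher and 20 lower among 10276 tested, 2 of them (Scd1 and Klhl11) by at least 2-fold, and 1969 had an unadjusted p under 0.05. The higher share of the called genes was 42.9%, against 68.8% of 16 genes with TPM scaling and 32.4% of 37 with median-of-ratios scaling. Across genes, the change went with GC content (Spearman 0.57) and gene length (−0.51), where genes are not independent replicates, and with that trend removed 484 genes were called, among them 15 of the 15 higher and 19 of the 20 lower. The count was 1164 with the replicate number as a block, and it rested on single libraries. It was 1 without untreated replicate 2, untreated replicate 3 or anti-CD36 replicate 3, 5 without anti-CD36 replicate 1, 7 without LPS replicate 2 or LPS+anti-CD36 replicate 1 or 2, 8 without LPS+anti-CD36 replicate 3, 18 without anti-CD36 replicate 2, 62 without untreated replicate 1 and 131 without LPS replicate 1. In a limma fit of the untreated and anti-CD36 libraries alone no gene passed, and Scd1 had an adjusted p of 0.066 (its range over 27 settings was 2.09e-05 to 0.066).

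**Figure D1:**
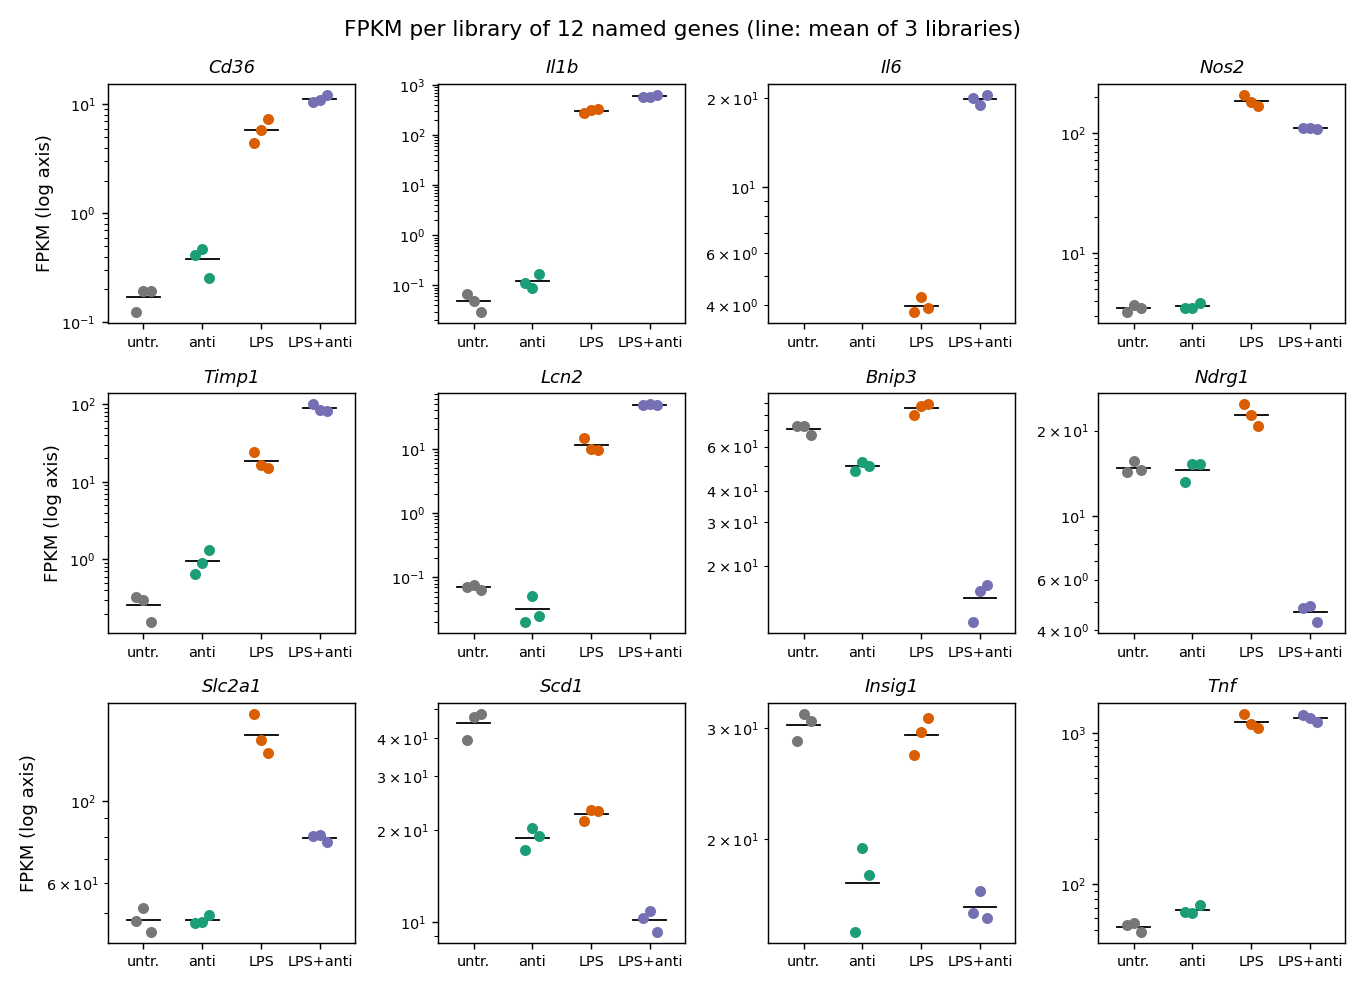
FPKM of 12 named genes per library (log axes), with a line at the mean of the 3 libraries of each group; Il6 is shown only with LPS, since its other values belong to another entry. Bnip3 stood at 14.8 with LPS and antibody against 85.4 with LPS, and Il6 at 19.9 against 3.96.

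Adding the antibody to LPS was compared with LPS alone, to show what it changed in activated cells. Il6 (chromosome 5, 30013114 to 30019981), an acute-phase cytokine, rose from 3.96 ± 0.241 to 19.9 ± 0.845 FPKM (log2 change 2.07, adjusted p = 8.58e-08). Timp1, an inhibitor of matrix metalloproteinases, rose from 18.6 ± 4.89 to 88.5 ± 9.56, and Lcn2, an iron-withholding protein, from 11.3 ± 2.79 to 48 ± 0.865. Bnip3 (chromosome 7, 138890836 to 138909519), a mitophagy receptor, fell from 85.4 ± 4.25 to 14.8 ± 2.59 (log2 change −2.46, adjusted p = 1.97e-07), and Ndrg1, a stress-responsive gene, from 22.8 ± 1.97 to 4.63 ± 0.324. Cd36 rose from 5.86 ± 1.47 to 11.2 ± 0.974 (log2 change 0.85, adjusted p = 0.00214).

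Of 17 tested inflammatory cytokine genes 12 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone (median 0.49, adjusted p = 3.02e-08, and 0.0149 with an estimated correlation, or 0.0606 with the GC content and gene length trend removed as well). Il1b rose from 306 ± 25.9 to 596 ± 36.3, Il1a from 222 ± 46.1 to 476 ± 40.9 and Csf2, a myeloid growth factor, from 34.2 ± 0.782 to 69.8 ± 1.65. Of 14 chemokines 12 rose, and 13 adjusted over the list alone (median 0.55, adjusted p = 1.43e-09, or 0.142 with an estimated correlation), such as Cxcl2 (log2 change 1.28) and Ccl22 (1.03). Of 20 classical activation effectors 10 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone (adjusted p = 1.32e-05, and 0.0295 with an estimated correlation, or 0.0576 with that trend removed as well). The gene that fell was Nos2, from 188 ± 20.8 to 110 ± 0.678 (adjusted p = 0.000222). Of 24 NF-kB targets 8 rose and 2 fell, and 10 rose and 4 fell adjusted over the list alone (adjusted p = 0.0164, or 0.262 with an estimated correlation). Tnf stood at 1252 ± 64.7 against 1176 ± 134 (adjusted p = 0.513) and Cd14 at 1987 ± 106 against 1569 ± 266 (adjusted p = 0.0953), while Tlr4 fell from 7.07 ± 1.7 to 3.98 ± 0.513 (adjusted p = 0.0227, not past in 7 of 27 settings). Of 39 interferon-stimulated genes 2 rose and 3 fell (adjusted p = 0.377).

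Glycolysis was the list with the smallest set p in camera with the preset correlation. With an estimated correlation and in fry it was inflammatory cytokines. Of the 24 glycolysis genes 17 fell and 0 rose, and 18 fell adjusted over the list alone (median −0.54, adjusted p = 6.26e-13, and 0.0318 with an estimated correlation). Slc2a1 fell from 152 ± 18.9 to 79.6 ± 1.87, the phosphofructokinase Pfkl from 28.5 ± 4.93 to 13.8 ± 0.357 and Pfkfb3, which makes its activator, from 12.6 ± 1.79 to 5.01 ± 0.117. Bnip3, which is on this list as well, is not a glycolytic enzyme. Of 25 genes of cholesterol synthesis and uptake 9 fell, and 15 fell and 1 rose adjusted over the list alone (median −0.32, adjusted p = 4.51e-06, and 0.0295 with an estimated correlation), and of 16 genes of fatty acid synthesis 7 fell, and 10 fell and 1 rose adjusted over the list alone (median −0.31, adjusted p = 0.000103, or 0.109 with an estimated correlation). Scd1 fell from 22.5 ± 0.981 to 10.1 ± 0.801, Scd2 from 180 ± 2.89 to 60.8 ± 3.03 and Insig1 from 29.3 ± 2.02 to 15.6 ± 0.82.

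Of 6 alternative activation markers tested, out of 20 listed, 4 fell (adjusted p = 0.00125, and 0.0448 with an estimated correlation). They were Vegfa, the growth regulator Myc, the transcription factor Egr2 and the fungal receptor Clec7a. Myc and Egr2 are also on the list of immediate early genes, so these falls do not show a change of the whole marker list. Of 26 immediate early genes 10 fell and 5 rose (adjusted p = 0.0272, or 0.636 with an estimated correlation), with Egr1 falling from 34.2 ± 3.87 to 13.6 ± 1.18 and Nr4a1 rising from 2.54 ± 0.184 to 7.1 ± 0.586. Of 30 stress response genes 9 fell and 1 rose (adjusted p = 0.00557, or 0.221 with an estimated correlation), such as the oxidoreductase Ero1a (from 152 ± 34.8 to 49.9 ± 5.41). Of 30 genes of DNA replication 6 rose (adjusted p = 0.0383, or 0.301 with an estimated correlation), such as Ccne1 (0.47). Of 36 oxidative phosphorylation genes 3 rose (adjusted p = 0.000202, or 0.624, with the other direction in 1 of 27 settings) and of 32 ribosomal protein genes 4 rose (adjusted p = 2.18e-05, or 0.513), each second value with an estimated correlation. The other large changes were rises of Akap12 (log2 change 2.00), Csta3 (1.81) and Cstdc4 (1.39) and falls of Ccng2 (−2.05), Adm (−1.85), Mgarp (−1.77) and Bnip3l (−1.61).

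**Figure D2:**
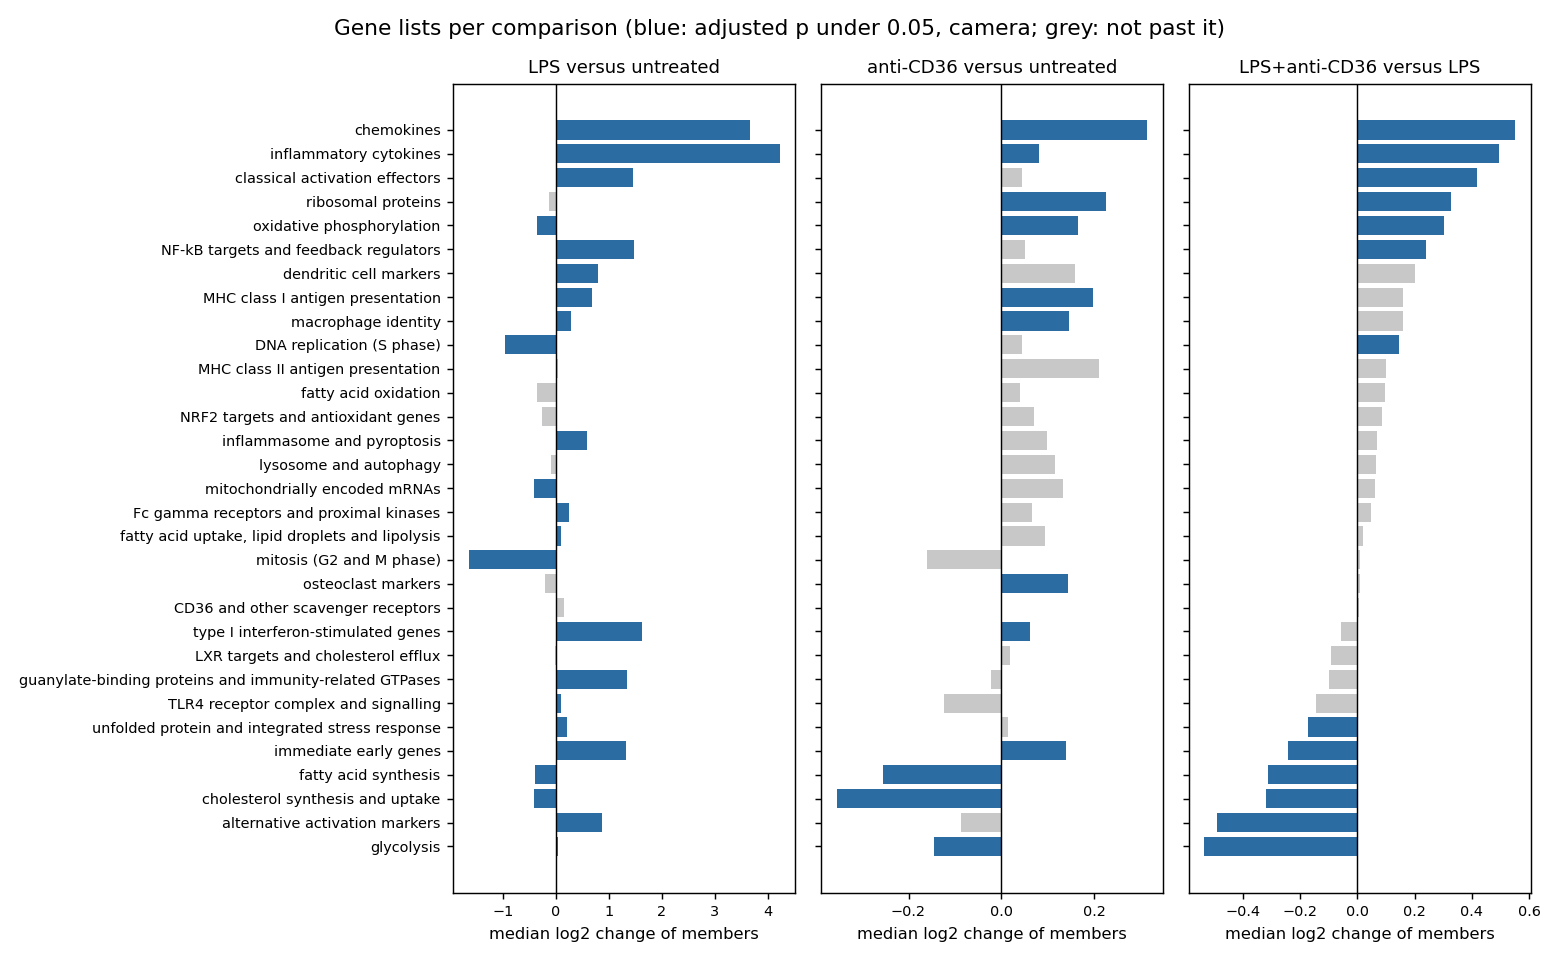
Median log2 change of the tested members of each of 31 gene lists in 3 comparisons (each panel has its own axis), blue where the set test passed. With the antibody added to LPS, glycolysis had a median of −0.54 and chemokines one of 0.55.

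Over all genes, 755 rose and 837 fell among 10277 tested, 99 of them by at least 2-fold (27 higher, 72 lower). The higher share was 47.4%, or 32.9% of 1177 genes with TPM scaling. The change went with GC content (Spearman 0.39 across genes) and gene length (−0.50), and with that trend removed 2648 genes were called, 605 of the 755 higher and 734 of the 837 lower among them. The count was 3970 without LPS replicate 1, 570 without LPS replicate 2, 735 without LPS replicate 3, and 614, 551 and 822 without LPS+anti-CD36 replicates 1, 2 and 3. With the replicate number as a block it was 3646. Of the 31 lists 13 passed, 7 up and 6 down, and 5 passed with an estimated correlation. Splits that mixed the LPS and LPS+anti-CD36 libraries passed up to 12, so here too the number of lists says little by itself.

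**Figure D3:**
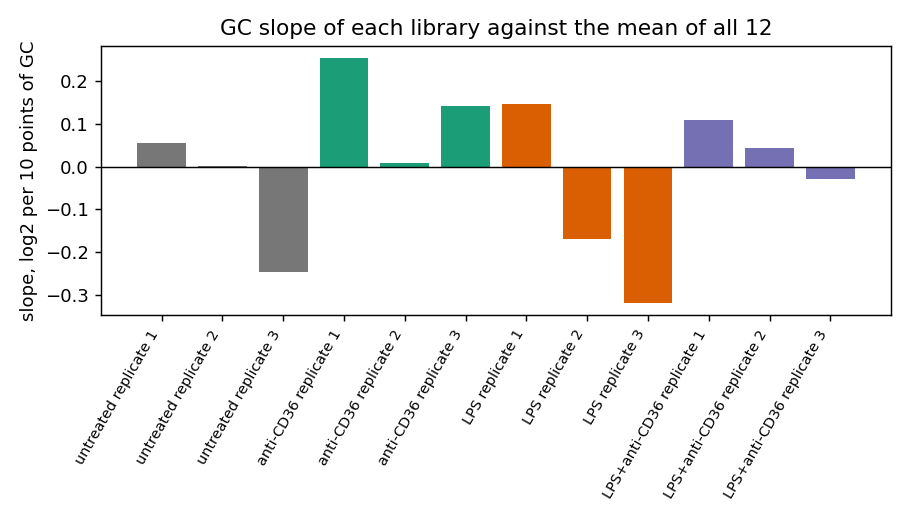
Slope of each library's log2 values on GC content, against the mean of all 12 libraries (bars, log2 per 10 points of GC, gene length in the same model). The slopes ran from −0.317 in LPS replicate 3 to 0.253 in anti-CD36 replicate 1.

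The GC slope of the libraries differed between replicates of one group. Its mean was −0.063 ± 0.161 in untreated, 0.134 ± 0.122 in anti-CD36, −0.113 ± 0.237 in LPS and 0.042 ± 0.069 in LPS+anti-CD36 libraries. Of the within-group variance 70.6% lay on 1 component. Without the 3 libraries of lowest slope (untreated replicate 3, LPS replicates 2 and 3) the antibody alone called 12 genes. The antibody added to LPS called 524, with 1 LPS library left, which is assumed to vary like the libraries of the other groups.

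The 2 antibody-treated groups were compared to show the LPS response in the presence of the antibody. Cxcl2 rose from 1.29 ± 0.0657 to 1036 ± 102 FPKM, Il1b from 0.123 ± 0.044 to 596 ± 36.3 and Acod1 from 7.42 ± 1.15 to 1342 ± 64.4. Nos2 rose from 3.58 ± 0.198 to 110 ± 0.678, Tnf from 67.5 ± 4.41 to 1252 ± 64.7 and Cd36 from 0.379 ± 0.111 to 11.2 ± 0.974 (log2 change 3.15, adjusted p = 4.49e-09). Cd24a fell from 32.1 ± 2.76 to 2.03 ± 0.271, Trem2 from 43.8 ± 7.39 to 4.9 ± 0.157 and Cldn11, a tight junction protein, from 87.7 ± 6.33 to 13.6 ± 0.26. All 16 cytokine genes, 13 of 14 chemokines, with 1 lower, and 37 of 39 interferon-stimulated genes rose, with set adjusted p of 1.33e-22, 1.26e-16 and 2.15e-25. Of the genes of DNA replication 29 of 30 fell, and of mitosis 30 of 30 (adjusted p = 7.45e-10 and 9.23e-15). In glycolysis 12 of 24 genes fell and 2 rose (adjusted p = 0.203). In all 1670 genes were higher and 3212 lower among 10276, 918 of them by at least 2-fold, with a median over all genes of −0.12. With median-of-ratios scaling 2245 were higher and 2217 lower, 50.3% higher in place of 34.2%. Of the 31 lists 18 passed, and 8 with an estimated correlation.

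The interaction asked whether the LPS change differed with the antibody. Bnip3 stood at 70.4 ± 3.34 FPKM untreated, 50.1 ± 1.9 with antibody, 85.4 ± 4.25 with LPS and 14.8 ± 2.59 with both, an interaction of −1.98 on the log2 scale (adjusted p = 0.000135). The interaction was −2.05 for Ndrg1 (adjusted p = 1.1e-05), −1.57 for Mgarp and −1.49 for Egr1 (each adjusted p = 0.000143), and −0.80 for Nos2 (adjusted p = 0.00572). It was 1.95 for Akap12, a kinase scaffold (adjusted p = 5.67e-06), 2.06 for Lcn2 and 1.06 for Csf2 (each adjusted p = 0.000143), 1.13 for Gstt4 (adjusted p = 0.00017) and 0.86 for Il1b (adjusted p = 0.00212). Cd36 had a value of 0.62 (adjusted p = 0.239), Tnf −0.26 (0.715), Cd14 0.07 and Tlr4 −0.26 (each adjusted p = 1). In glycolysis 4 of 24 genes were lower, and 15 adjusted over the list alone (adjusted p = 1.35e-17, and 0.0202 with an estimated correlation), while 6 of 16 cytokine genes were higher, and 8 higher and 2 lower adjusted over the list alone (adjusted p = 2.15e-05, and 0.0202). The lists of cholesterol and fatty acid synthesis had 0 genes called and set adjusted p of 0.233 and 0.478.

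In all 51 genes had a higher and 81 a lower interaction among 10276, and 884 had an unadjusted p under 0.05. The higher share was 38.6%, or 26% of 104 genes with TPM scaling. Calls among the higher ones depended on the scale: limma-voom on the recovered fragments called 5 higher and 67 lower, with 63 of the 81 lower ones among them. There Csf2 (1.94), Lcn2 (3.20) and Gstt4 (1.84) had larger values but were not called (adjusted p = 0.517, 0.0834 and 0.678, in each case the highest over its settings), Il1b had −0.22 and Cd36 −0.23, and Akap12, Ndrg1, Bnip3, Mgarp, Egr1 and Nos2 were called in the same direction. The count was 78 without LPS replicate 2, 61, 66 and 64 without LPS+anti-CD36 replicates 1, 2 and 3, 77 without anti-CD36 replicate 3 and 83 without untreated replicate 2.

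Overlaps between comparisons were counted next. Of the genes that LPS raised, 305 were lowered by adding the antibody, such as Nos2, Slc2a1 and Vegfa, and 223 were raised further, such as Il1b and Cxcl2, against 139.3 and 125.6 for independent lists. Of the genes that LPS lowered, 313 were raised by adding the antibody and 167 were lowered further, such as Scd1 and Tlr4, against 250 and 277.2 for independent lists. LPS alone and the antibody alone raised 10 genes in common, against 2.5, Cxcl2 and Ccl3 among them, and lowered 5, against 6.6. The 305 became 671, 131 and 181 without LPS replicates 1, 2 and 3, and 166, 151 and 193 without LPS+anti-CD36 replicates 1, 2 and 3. The 313 became 999, 86 and 111 without those LPS replicates, 86, 76 and 138 without those LPS+anti-CD36 replicates, 190 without untreated replicate 2 and 207 without anti-CD36 replicate 3. The 10 raised in common became 33 without LPS replicate 1, 4 without anti-CD36 replicate 2, 2 without LPS replicate 2 or any LPS+anti-CD36 replicate, and 0 in limma without untreated replicate 2 or 3 or anti-CD36 replicate 1 or 3. The compared groups shared libraries, which can give overlap by itself, and the figures for independent lists ignore this. The median of 100 simulations with unchanged groups was 0 for each, and 1 simulation reached 2653 and 1757 for the first pair of opposite changes. No gene was changed in the simulations, whereas LPS alone called 5113 here. Neither reference therefore matches these data, and whether the overlaps exceed what shared libraries give was not settled. The correlation across genes of the LPS and antibody changes was 0.065 (0.525 in the simulations), and that of the LPS change with the change on adding the antibody was −0.065 (−0.455).

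Markers of other cell types were low. Among lymphocyte, granulocyte and mast cell, and fibroblast and epithelial markers, the untested genes reached at most 0.761, 0.547 and 0.42 FPKM. The exceptions were Lck, a kinase also found outside lymphocytes, with 2.1 FPKM untreated and 6.27 with LPS, and Csf3r, a receptor also found on macrophages, with 1.2 to 1.55 FPKM. Mitochondrially encoded genes held between 3.42% and 5.12% of the fragments of a library.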

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

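The tests of the GC content and gene length trend (with their bar), of endotoxin and of stronger LPS stimulation, limma-voom on recovered fragments, and the split counts with the trend or the antibody effect removed, were chosen only after the result was seen. The hypoxia-inducible factor list was picked because some of its known members had been seen to fall.

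The change that LPS brought differed between cells with and without the antibody, by the test of the interaction, for 132 genes and 11 gene lists. Of 233 named genes 38 differed, 20 higher and 18 lower. Genes with a higher value on the log2(FPKM + 1) scale were Lcn2 (interaction of 2.06 on the log2 scale), Akap12 (1.95), Csta3 (1.82), Timp1 (1.59), Cstdc4 (1.38), Gstt4 (1.13), Fpr2 (1.06), Nr4a1 (1.01), Ass1 (0.94), Fpr1 (0.89), Srxn1 (0.50) and Gclm (0.43). The cytokines and chemokines among them were Ccl17 (1.28), Il1a (1.12), Csf2 (1.06), Csf3 (1.00), Il1b (0.86), Ccl7 (0.79) and Ccl22 (0.74), with the NF-kB inhibitor Nfkbie (0.74). Genes with a lower value were Ndrg1 (−2.05), Bnip3 (−1.98), Adm (−1.87), Ccng2 (−1.66), Mgarp (−1.57), Egr1 (−1.49), Trib3 (−1.29), Bnip3l (−1.25), Atf3 (−1.16), Slc2a1 (−0.91), Ak4 (−0.89), Chac1 (−0.88), Nos2 (−0.80), Gpat3 (−0.79), Pfkfb3 (−0.75), Vegfa (−0.74), Pfkl (−0.74) and Lpin1 (−0.66). With limma-voom on recovered fragments 18 of the 20 higher genes kept their direction, 16 with a larger value, though only 2 passed, Akap12 and Nr4a1, and 2 had the other direction, Il1b (−0.22) and Csf3 (−0.25). Of the 18 lower genes 14 passed there, and 0 had the other direction.

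The lists that differed upward were inflammatory cytokines (adjusted p = 2.15e-05), chemokines (0.00011), classical activation effectors (1.14e-05), NF-kB targets (0.0236), mitosis (0.0264) and ribosomal proteins (0.022). Those that differed downward were glycolysis (1.35e-17), immediate early genes (2.76e-07), alternative activation markers (1.14e-05), the stress response (0.000226) and interferon-stimulated genes (0.000921). With an estimated correlation 4 of the 11 passed: cytokines, classical activation, alternative activation and glycolysis. These list values are given on the log2(FPKM + 1) scale only, where Il1a and Il1b lie near 0 without LPS. With limma-voom none of the cytokines and chemokines named above passed, so the upward cytokine and chemokine lists may depend on the scale. Of 100 drawn splits by antibody within each LPS state, 11 gave at least as many genes as the real 132, and the highest other gave 3610. With the trend removed 11 of 100 gave at least the real 401, and the highest other gave 3248. All 11 in each case kept the LPS libraries apart from the LPS+anti-CD36 libraries, while the 87 that mixed them gave at most 0, or 3 with the trend removed. By construction the first kind of split carries the antibody effect in LPS-treated cells into the interaction, so these counts do not bear on chance. With the average antibody effect of each gene removed first, 1 of 100 splits, the real one, gave 132, and the highest other gave 1. With the trend removed too, 1 of 100 gave 401, and the highest other gave 2. These counts do not exclude chance. The removed effect was estimated from the real groups, and the interaction of each gene was left in the values. The other splits therefore carried that interaction in their spread, which lowers their counts.

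In LPS-treated cells the antibody lowered glycolysis genes and raised cytokine genes. For glycolysis, a GC content and gene length trend as the whole cause was argued against by the values with the trend removed. Their median was −0.569 (−0.916 to −0.385, adjusted p = 4.97e-17, or 0.0259 with an estimated correlation), from −0.535 before. For cytokines the median was 0.439 (0.167 to 0.851), from 0.494. The cytokine set test passed with the preset correlation (adjusted p = 7.18e-05) but not with an estimated one (0.0606). A trend as the whole cause of the cytokine change was thus argued against with the preset correlation only, and a trend behind part of it stayed open. An earlier bar, on the size of the change, had left the cytokine part undecided. Endotoxin in the antibody enough to raise LPS targets by 0.5 was argued against by 117 LPS targets with at least 1 FPKM in untreated cells. Their median with the antibody alone was 0.177 (0.138 to 0.234, SD of the members 0.296). A smaller amount stayed open, since 78.6% of them lay above 0, with 3 called higher and 0 lower. Targets under 1 FPKM in untreated cells, such as Cxcl2, were not in this set. The test of stronger LPS stimulation, on genes that LPS raised or lowered, did not settle it. The glycolysis genes argued against it as the cause of both parts only if stronger stimulation moves genes further the way LPS moved them. No LPS dose or time series was there to check that. LPS alone raised 8 of the 24 glycolysis genes and lowered 3 (median 0.04), while the antibody added to LPS lowered 17 and raised 0 (median −0.535). For the cytokine part stronger stimulation stayed open. The 143 genes that LPS raised had a median of 0.264 (0.159 to 0.335, 55 called higher and 9 lower). The 325 that LPS lowered had one of 0.058 (0.029 to 0.092, 26 called higher and 23 lower). That was not the fall it predicts, but the members varied widely (SD 0.293). Of 39 interferon-stimulated genes, 38 of them raised by LPS, adding the antibody raised 2 and lowered 3. A candidate explanation for the glycolysis part is lower activity of hypoxia-inducible factor, since 12 of 18 of its targets outside that list fell (median −0.59, −0.835 to −0.433), a hypothesis only, with cell density, medium and the effect of any antibody untested.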

How the results depend on the processing

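The removal of the GC content and gene length trend, the GC slope as a covariate, limma-voom on recovered fragments and the fit without 3 libraries were chosen only after results were seen. Of 11282 pairs of a named gene and a setting, 10737 kept direction and side of the threshold, 416 lost the call, 114 gained one and 15 changed direction. Calls lost in at least 1 setting numbered 2 of 122 for LPS, 17 of 17 for the antibody alone, 39 of 93 for the antibody added to LPS, 5 of 123 for LPS with antibody in both groups and 4 of 10 for the interaction. Those 10 were only the called genes named in the interaction itself, most of them chosen for a small p. Of all 38 named genes with an interaction, limma-voom called 2 of the 20 higher and 14 of the 18 lower. The edgeR and DESeq2 alternative was run on the fragments recovered from the FPKM steps and gave widely differing counts for the antibody alone. Its values are not reported here, since count tools were not accepted for an FPKM table. Depth differed by at most 1.8 times. Causes were not tested unless stated.

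Values are given in the order antibody alone, antibody added to LPS, LPS-raised genes lowered by adding it, LPS-lowered genes raised by adding it, genes raised by both LPS and antibody, interaction. With the GC and length trend removed they were 484, 2648, 657, 502, 132 and 401, with 7 lists for the antibody alone, and Nos2 there had −0.03 and Tnf, antibody added to LPS, −0.11. With the GC slope as a covariate they were 720, 3626, 630, 1103, 218 and 1155, with Nos2 −0.02, Rps2 0.00 and Rpl19 −0.01 for the antibody alone and Tnf −0.01 for adding it. With the replicate number as a block they were 1164, 3646, 568, 911, 179 and 212. The labels gave no pairing of replicate numbers. Same-numbered pairs correlated from −0.32 to 0.81, 10 of 18 above 0.1, and 7 of 12 libraries correlated best with their own number. All pairs of replicate 1 lay between 0.45 and 0.78, and those of replicate 3 without its anti-CD36 library between 0.54 and 0.81. Without the 3 libraries of lowest GC slope, which leaves 1 LPS library, assumed to vary like the other groups, the first 5 were 12, 524, 145, 74 and 5, with Tnf −0.08 for adding the antibody and Cd14 −0.06 for the interaction. With only the compared libraries in the limma fit, which have fewer residual degrees of freedom, they were 0, 940, 182, 126 and 0.

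By construction, a 2-fold minimum lowered the counts, to 957 for LPS, 2, 99, 17, 0, 0 and 46 in the order above, and 918 for LPS in antibody-treated cells. TPM scaling gave 16 for the antibody alone and 163 LPS-lowered genes raised, with Nos2 −0.03 and Tnf −0.02, and quantile normalization gave Tnf −0.04. The filter at FPKM 5, which tests fewer genes, gave 85 for the interaction. No filter gave 5 genes raised by both. With limma-voom the interaction called 72 genes, with Cd36 at −0.23 and Il1b at −0.22. With an estimated correlation 10, 1 and 5 lists passed for LPS, the antibody alone and the antibody added to LPS, and with fry 6 for the antibody alone.

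Leaving out 1 library at a time gave 1 to 131 genes for the antibody alone, lowest without untreated replicate 2 and highest without LPS replicate 1. The antibody added to LPS gave 551 without LPS+anti-CD36 replicate 2 to 3970 without LPS replicate 1, and the interaction 61 without LPS+anti-CD36 replicate 1 to 157 without LPS replicate 1. LPS-raised genes lowered numbered 131 to 671, LPS-lowered genes raised 76 to 999 and genes raised by both 0 to 33, each highest without LPS replicate 1. LPS gave 4298 to 5447 and LPS in antibody-treated cells 3992 to 5442. Cd14 in the interaction ran from −0.04 without LPS replicate 3 to 0.20 without LPS replicate 1, with 0.00 without untreated replicate 1.

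Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave the largest count. The real and highest other gene counts were 5113 and 1866 for LPS, 35 and 0 for the antibody alone, 1592 and 1 for adding it and 4882 and 0 for LPS in antibody-treated cells. The list counts were 23 and 21, 12 and 10, and 13 and 12 for the first 3. The number of lists that passed therefore hardly separated the real groups from mixed ones.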

Other observations

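The tests of the GC content and gene length trend on the sterol genes, and of the Il6 values, were chosen only after the result was seen.

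LPS alone changed further macrophage genes. The haem oxygenase Hmox1 rose from 65.8 ± 7.52 to 421 ± 39.4 FPKM, the costimulatory receptor Cd40 from 0.295 ± 0.05 to 22.6 ± 4.73 and the inflammasome sensor Nlrp3 from 12.1 ± 1.27 to 48.8 ± 1.08. The scavenger receptor Msr1 rose from 17.5 ± 1.74 to 73.6 ± 14.1, the gelatinase Mmp9 from 0.757 ± 0.0412 to 22.6 ± 3.35 and the transcription factor Irf8 from 7.11 ± 0.777 to 33.2 ± 4.7. Gpnmb, a transmembrane glycoprotein, fell from 134 ± 7.85 to 26.1 ± 2.98. Among stress response genes, Chac1 rose from 1.79 ± 0.17 to 19.1 ± 3.54 and Atf3 from 4.91 ± 0.242 to 81.4 ± 3.27 (n = 3 libraries per group).

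With the antibody alone, 4 of 25 genes of cholesterol synthesis and uptake fell over all genes tested, and 17 adjusted over the list alone. A GC content and gene length trend as the whole cause was argued against by the cholesterol list, whose median was −0.338 with the trend removed (−0.466 to −0.262), from −0.355 before, with 16 of its genes lower and a set adjusted p of 4.76e-19, or 0.00423 with an estimated correlation. A biological effect of the antibody through CD36 and an effect of any antibody or of its buffer stayed open, since the groups held no isotype control. Cd36 mRNA was low in the cells without LPS, from 0.1235 FPKM in untreated replicate 1 to 0.4713 in anti-CD36 replicate 2. CD36 protein was not measured here, and the labels do not say that the antibody blocks CD36.

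The Il6 values in libraries without LPS were not used. At the Il6 gene length 0 of these 6 were a whole number of fragments, against 6 of 6 with LPS, so they were not counted for Il6 itself. In 6 of 6 they equalled, digit for digit, the values of the lincRNA Gm10874 (chromosome 5, 138363719 to 138388287), so they may have been copied from that entry. The Il1b value of untreated replicate 2 equalled the mean of the other 2 replicates to 9 decimals, at 2.78 fragments, the 1 such value among 158901 searched.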
